A study of Macaca fascicularis with 28 samples.

How the data were processed

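Total RNA of peripheral blood mononuclear cells from 7 cynomolgus macaques was measured on 28 Affymetrix Rhesus Genome arrays (1 colour, biotin label), 1 array per monkey at each of 4 time points, per the labels. Rhesus probes were thus hybridised with RNA of a related macaque species. The deposited table holds, per the submitters' processing notes, MAS5 values, which are probe set intensity (the MAS5 signal) on a linear scale; the MAS5 version is not given in the sources used here. The authors had scaled the intensity values of each array before deposit, as the values themselves show: the mean after trimming 2% of the probe sets at each end was 500.0 on all arrays, so no further scaling was applied. MAS5 subtracts mismatch from perfect match probes and so leaves low signals noisy, and scaling to a trimmed mean hides any change shared by most transcripts. Detection calls, scan dates and raw probe files were not used here, so scan batches were not tested. No 2 arrays held identical values.

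Of 52865 probe sets in the table, 158 controls were left out. Values below the 10th percentile of all pooled values (a signal of 36.1) were raised to it, and log2 was taken. A probe set was tested when its mean log2 value over all arrays was at or above the median of such means, which is a signal of 244 and kept 26354 probe sets; 0.224% of their values lay at the floor. Gene names came from the platform annotation of 2016: 24956 probe sets had 1 symbol, 361 had several and 27390 had none, and of those tested 14702, 253 and 11399. The tested probe sets with 1 symbol stood for 9338 genes. A RefSeq gene table of the crab-eating macaque held the symbol of 22600 listed probe sets and the Entrez identifier of 0, so symbols were kept as the annotation gives them, and no gene was named from a probe set with several symbols or none. PRF1, IL7R and other familiar genes had no measured probe set of that name. The annotation names no probe set of a virus and none of the sex-linked genes planned for the identity check, so that check rests on correlations between arrays.

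Time points were compared with limma (3.58.1, in R 4.3.3): lmFit on all 28 arrays with the 4 time points and the monkey as a fixed block, then eBayes with a mean-variance trend, which left 18 residual degrees of freedom and a median prior of 7.37. The monkeys' numbers in the titles pair the arrays, since each number names 1 animal. Arrays of the same monkey also deviated together (mean r 0.204 over 42 pairs, from -0.0165 to 0.374, with 37 pairs over 0.1). Adjusted p-values follow Benjamini and Hochberg over the probe sets tested within a comparison, with 0.05 as the threshold. The 5 comparisons were weeks 2, 20 and 26 with baseline, week 26 with week 20 and week 20 with week 2.

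Groups of genes were 25 lists (interferon response, restriction factors, blood cell types, inflammation, immediate early genes, cell cycle, apoptosis, stress, ribosome, respiration and housekeeping) with 1 probe set per gene, the brightest of those with that gene as their only symbol. They were tested with camera at a preset correlation of 0.01, adjusted over 125 list tests. They were tested again with a correlation estimated from the residuals (camera with statmod 1.5.0), with fry, and with an exact two-sided permutation test that flips the sign of each monkey's mean change, for which 7 monkeys allow no p under 0.0156. Counts "adjusted over the list alone" apply Benjamini and Hochberg within a list. Spike-in signal and the ratio of 3' to 5' actin and GAPDH probe sets described array quality; 5 arrays with spike-in signal over 4 times the median array or an actin ratio over 3 were left out in an alternative chosen after the data were seen.

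The groups, comparisons, lists, all but 2 of the alternative settings and the rule for named genes were fixed before the data were examined. The rule takes probe sets that stand for a gene (1 symbol, the brightest of its probe sets, no LOC symbols). For each comparison with baseline and for week 26 with week 20 it names the 10 largest rises and the 10 largest falls among those at adjusted p under 0.05 that moved the same way in 7 of 7 monkeys. For each list described it names up to 4 members with the smallest adjusted p, and always 18 marker genes (among them MX1, ISG15, CXCL10, MKI67, TOP2A, GZMB, GZMK, PRF1, CD8A, CD4, IL7R, CCR7, MS4A1, CD14, NKG7, PPBP, HBB), of which 14 were measured. The text prints part of these genes, and which part was decided after their values were seen. The genes named for week 20 with week 2 outside the rule, SAMSN1 and OAS1, were also chosen after their values were seen.

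The procedure was tested on simulated data for the real 26354 probe sets, with 200 of them changed, 100 by 2-fold and 100 by 4-fold. For week 2 with baseline it recovered 46 of the 2-fold and 89 of the 4-fold changes with 9 false calls, for week 20 with baseline 58 and 86 with 11, and for week 26 with baseline 44 and 90 with 4. For week 26 with week 20 it recovered 45 and 90 with 8 false calls, and for week 20 with week 2 it recovered 43 and 97 with 9. A shifted list was found in each comparison and 0 of the other 24 lists were called. The simulated spread was drawn independently for each probe set, so list members did not move together as they may on real arrays. The simulation therefore cannot show how often lists are falsely called in the real data. There, 44 of 125 list tests passed as reported and 4 with an estimated correlation. With 7 arrays per time point the median SE of a log2 change was 0.26, so many 2-fold changes of single genes go undetected.

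The alternatives were no monkey block, the monkey as a random effect, quantile normalization, median centring, no filter or a stricter filter (mean log2 at or above the 75th percentile), no floor, a floor at the 25th percentile, a pseudocount of 16, eBayes with no trend or made robust, only the 2 time points compared, array weights, a threshold of 0.01, a 2-fold minimum, the mean of all probe sets of a gene, an estimated correlation for lists and leaving out each monkey in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.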

Results

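Gene expression was measured in peripheral blood mononuclear cells of 7 cynomolgus macaques infected in vivo with SIVmac251, a simian immunodeficiency virus that models HIV infection. Each monkey was sampled before infection (baseline) and at weeks 2, 20 and 26 after it, which gave 7 arrays at each of 4 time points and 28 Affymetrix Rhesus Genome arrays in all. Drug therapy started at week 24, so the week 26 samples were taken 2 weeks into therapy; the drug is not named in the sources used here. Every monkey was infected and every monkey was treated. Time after infection and therapy therefore change together between weeks 20 and 26. No uninfected animals were sampled at the later visits. In the comparisons with baseline, infection therefore cannot be told apart from visit, sample handling or array batch. Each array holds MAS5 signals for 52865 probe sets, already scaled by the authors, and the median signal per array ran from 236 to 355. The number of arrays limits the precision. Below, the change of a gene is a log2 difference ± SE from the limma fit with n = 7 monkeys. The change of a gene list is the mean log2 difference over its measured members ± SD over the 7 monkeys.

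The arrays were not of equal quality. Spike-in controls added during hybridisation read 17.0 times the median array at week 26 in monkey 3318, 11 times at week 26 in monkey 3319 and 4.18 times at week 20 in monkey 3336. A high ratio of 3' to 5' actin signal, a sign of RNA degradation, was seen at week 20 in monkey 3324 (5.40) and at week 2 in monkey 3334 (3.34). Arrays of the same monkey deviated together from the group means (mean r across probe sets 0.204 over 42 pairs, against -0.0327 over 252 pairs of different monkeys). These correlations are across probe sets, which are not independent replicates.

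The comparison of week 2 with baseline addressed acute infection before therapy. Interferon-stimulated genes, the antiviral programme of infected tissue, were higher as a list by 0.77 ± 0.81, with 36 of the 38 measured members above baseline and 6 of 7 monkeys higher (camera, adjusted p = 1.49e-25). This call was lost with a correlation between genes estimated from the data (adjusted p = 0.0957 with an estimated correlation). IFI27, an interferon-inducible gene, had a change of 3.65 ± 0.75. ISG15, a ubiquitin-like antiviral modifier, had a change of 2.62 ± 0.59, and IFIT3, which binds into complexes that restrain viral RNA, one of 1.69 ± 0.40. Markers of B cells, which make antibody, were lower as a list by -0.64 ± 0.83 in 6 of 7 monkeys (adjusted p = 0.236 with an estimated correlation), with MS4A1 (CD20) at -1.42 ± 0.37 and CD79A, a chain of the B cell receptor, at -1.09 ± 0.31. No single probe set passed limma's test: 0 were called at adjusted p under 0.05 and the smallest adjusted p was 0.0770. At unadjusted p under 0.05 there were 1758 probe sets, against 1317.7 by chance.

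Monocyte markers were higher at week 2 as a list by 0.77 ± 0.75 in 6 of 7 monkeys (adjusted p = 0.275 with an estimated correlation), led by the calcium-binding alarmins S100A8 (2.25 ± 0.54) and S100A9 (2.34 ± 0.57), the lectin FCN1 (1.43 ± 0.35) and CSF3R, the receptor for granulocyte colony-stimulating factor (1.16 ± 0.29). CD14, the lipopolysaccharide co-receptor of monocytes, stood at 1.01 ± 0.33. Inflammatory cytokines and NF-kappaB targets rose by 0.61 ± 0.51 in 7 of 7 monkeys (adjusted p = 0.0248 with an estimated correlation). Their members included the chemokine CCL3 (2.11 ± 0.44), the secreted pattern-recognition protein PTX3 (1.30 ± 0.32) and the B cell survival factor TNFSF13B (1.13 ± 0.30). Interferon-gamma response genes were higher by 0.44 ± 0.38 (adjusted p = 0.386 with an estimated correlation), with the guanylate-binding protein GBP1 at 1.70 ± 0.39 and the chemokine CXCL10 at 1.11 ± 0.46. Cytotoxic effector genes were higher by 0.44 ± 0.55 (adjusted p = 0.333 with an estimated correlation), with the fractalkine receptor CX3CR1 at 0.64 ± 0.23 and the chemokine CCL5 at 0.65 ± 0.27. Dendritic cell markers were lower by -0.29 ± 0.35, with the lipid-presenting molecule CD1C at -1.15 ± 0.29, and platelet markers by -0.36 ± 0.70, with the platelet chemokine PPBP at -1.25 ± 0.44 and NRGN at -1.04 ± 0.34. These 2 lists had adjusted p = 0.333 and adjusted p = 0.477 with an estimated correlation, and platelet markers also lost their call without the 5 arrays of high spike-in signal or actin ratio (-0.33, adjusted p = 0.0829).

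Smaller shifts at week 2 were seen in oxidative phosphorylation genes (0.20 ± 0.14), retroviral restriction factors (0.21 ± 0.26), ribosomal protein genes (0.15 ± 0.27) and immediate early genes (0.13 ± 0.20). These 4 had adjusted p of 0.333 or more with an estimated correlation, so the inflammatory list alone of the 12 lists called kept its call. The immediate early shift passed in 9 of 21 alternatives, from 0.049 to 0.20, and the ribosomal shift was 0.24 without monkey 3336. Adjusted over the list alone, 21 of 38 interferon-stimulated genes, 14 of 25 monocyte markers, 7 of 17 inflammatory genes and 7 of 13 B cell markers passed, where 0 of each passed over all probe sets tested. The proliferation gene MKI67 stood at 0.41 ± 0.23, the T cell co-receptors CD8A at 0.38 ± 0.24 and CD4 at -0.05 ± 0.23. The smallest adjusted p among the 14 measured marker genes fixed in advance was 0.322, for ISG15.

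Monkey 3336 went against the other 6 at week 2. Its B cell list was 1.20 higher at week 2 than at baseline, while the other 6 monkeys had changes of -0.794 or lower. Its IFI27 change was -3.31, while that of monkey 3319, the highest, was 7.86. Of 186 probe sets that separated week 2 from baseline in the other 6 monkeys, 19 (10.2%) moved the same way in monkey 3336. For each other monkey against its own other 6, the share was 36.4% to 66.7%, over only 15 to 33 probe sets. The changes of monkey 3336 over all tested probe sets correlated at r = -0.184 with the mean of the other 6, against 0.0718 to 0.240 for the others. Without monkey 3336, limma called 135 probe sets, 55 higher and 80 lower. Among them were IFI27 (4.81, adjusted p = 0.000252), ISG15 (3.19, 0.00427), GBP1 (2.09, 0.00491), CCL3 (2.54, 0.00744), MS4A1 (-1.94, 0.00332), CD79A (-1.51, 0.0105) and PPBP (-1.84, 0.0128). Without monkey 3337, limma called 2. Camera with an estimated correlation was also run without monkey 3336, a fit chosen after the data were seen. The B cell list then passed (-0.95, adjusted p = 0.0126). The interferon-stimulated list (0.97, 0.0576) and the platelet list (-0.58, 0.114) did not. By limma without this monkey, NRGN passed (-1.58, 0.00415), and CD8A stood at 0.65 and did not pass (0.300). Monkey 3336 was singled out by its opposite changes in these same data. The calls made without it restate that choice and are no separate support for a week 2 change.

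**Figure D1:**
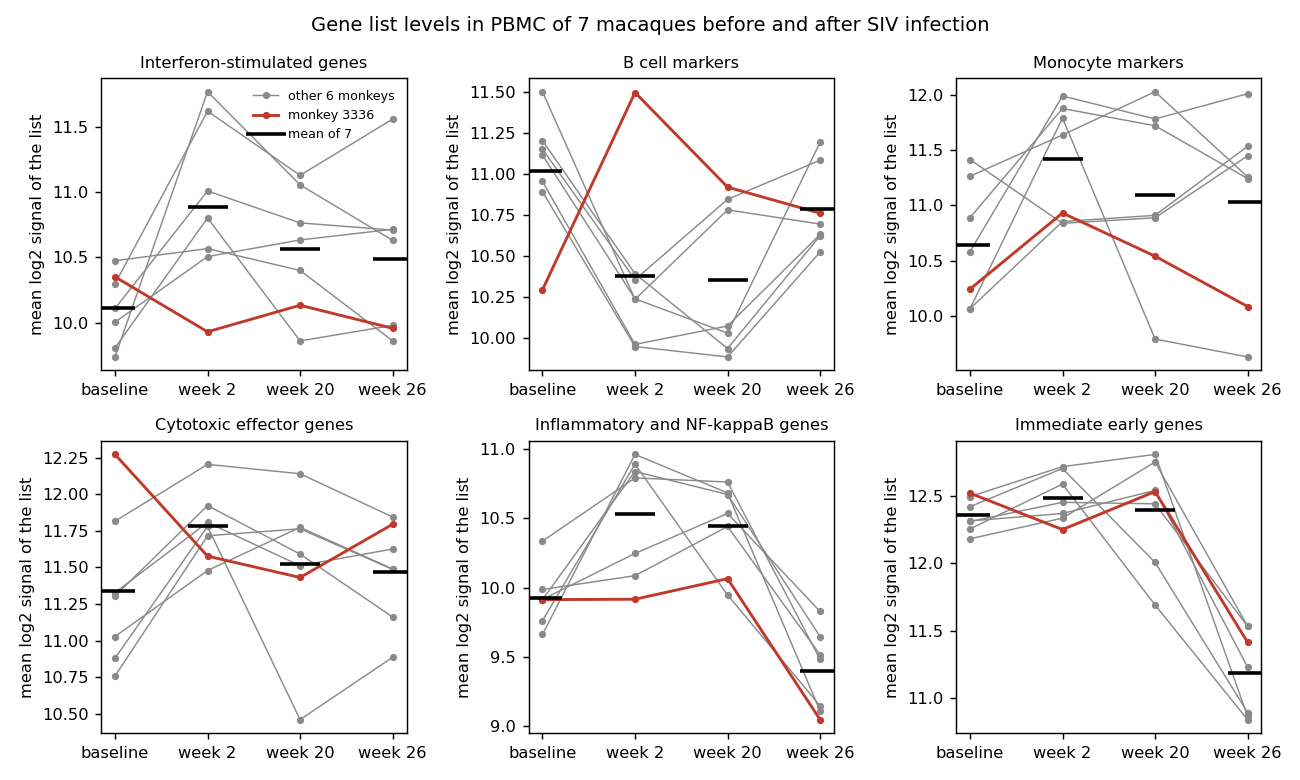
Mean log2 signal of 6 gene lists at the 4 time points, with 1 line per monkey, monkey 3336 in red, the other 6 in grey and the mean of 7 as a black bar. The B cell list of monkey 3336 was 1.20 higher at week 2 than at baseline, and the immediate early list lay below baseline at week 26 in 7 of 7 monkeys.

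**Figure D2:**
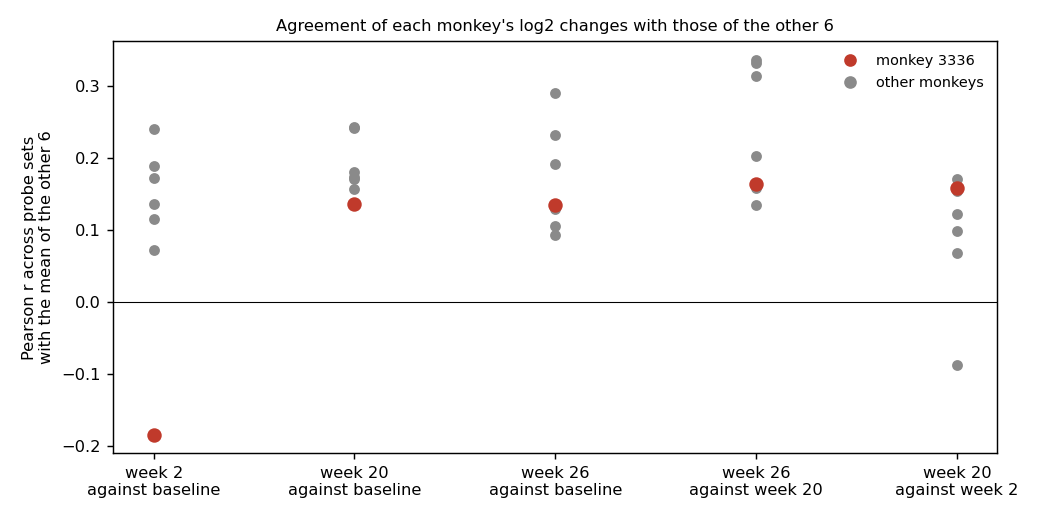
Pearson r across all tested probe sets between each monkey's log2 changes and the mean changes of the other 6, for the 5 comparisons. Each point is 1 monkey. Monkey 3336 (red) lay at -0.184 for week 2 against baseline, and monkey 3319 (grey) at -0.0873 for week 20 against week 2.

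The comparison of week 20 with baseline addressed established infection without therapy. PTX3, the pattern-recognition protein, rose by 1.88 ± 0.32 (adjusted p = 0.00686), SAMSN1, an adaptor that restrains B cell activation, by 1.0 ± 0.16 (0.00301), and ACSL1, which activates long-chain fatty acids, by 1.0 ± 0.23 (0.0486). Falls included DPEP2, a membrane dipeptidase (-1.79 ± 0.28, 0.00301), CCND3 (cyclin D3, -0.94 ± 0.15, 0.00301), FOXP1, a transcription factor of quiescent lymphocytes (-0.74 ± 0.15, 0.0177), and CD37, a tetraspanin of B cells (-0.65 ± 0.14, 0.0297). Each of these 7 genes moved the same way in 7 of 7 monkeys. B cell markers fell as a list by -0.66 ± 0.65 in 6 of 7 monkeys, with all 13 measured members below baseline, and naive and central memory T cell markers fell by -0.38 ± 0.31 in 7 of 7. With all 7 monkeys, both list calls were lost with an estimated correlation (adjusted p = 0.333 and adjusted p = 0.390 with an estimated correlation).

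Of 26354 probe sets tested, 123 passed limma's test at week 20, 32 higher and 91 lower, and 112 of them moved the same way in 7 of 7 monkeys. The larger number of falls was not seen without monkey 3324 (56 higher and 53 lower), 3333 (7 and 7) or 3337 (17 and 16). The further large rises were in FAM110A (1.82 ± 0.27), CHP2, a calcineurin B homologue (1.5 ± 0.33), NUFIP1 (1.15 ± 0.19), the potassium channel KCNJ13 (0.99 ± 0.19), the transcriptional repressor ZNF703 (0.98 ± 0.22), the translation release factor ETF1 (0.78 ± 0.15) and the transcription factor ETS2 (0.77 ± 0.17). The further large falls were in STAP1, an adaptor in B cell receptor signalling (-2.35 ± 0.54), TMEM39B (-1.53 ± 0.32), the phosphatase CDC14A (-1.46 ± 0.25), CPT1A, which brings fatty acids into mitochondria (-1.33 ± 0.29), the IgE receptor chain FCER1A (-1.27 ± 0.30), TSHZ1 (-1.16 ± 0.27), the sialyltransferase ST8SIA4 (-1.03 ± 0.21) and CCDC183 (-0.89 ± 0.19). A second probe set did not share the change for CHP2 (0.00), KCNJ13 (0.07), ETS2 (0.10) and CPT1A (0.41).

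Among the lists at week 20, 9 of 13 B cell markers passed adjusted over the list alone and 1, CD37, over all probe sets tested; CD79A stood at -1.16 ± 0.31, BLNK at -0.95 ± 0.28, FCRLA at -0.90 ± 0.27 and MS4A1 at -0.96 ± 0.37. Of 13 naive and central memory T cell markers, 5 passed adjusted over the list alone and FOXP1 passed over all, with ABLIM1 at -0.78 ± 0.19, PIK3IP1, an inhibitor of PI3 kinase, at -0.87 ± 0.26, and the kinase CAMK4 at -0.68 ± 0.22. The inflammatory list was higher by 0.52 ± 0.31 in 7 of 7 monkeys (adjusted p = 0.0727 with an estimated correlation), with 6 of 17 members passing adjusted over the list alone and PTX3 over all; the inflammasome gene NLRP3 stood at 0.84 ± 0.20 and the cytokine IL1B at 1.10 ± 0.34. Interferon-stimulated genes were higher by 0.46 ± 0.56 in 5 of 7 monkeys (adjusted p = 0.477 with an estimated correlation), with IFI27 at 2.73 ± 0.75, IFIT3 at 1.54 ± 0.40 and OASL, an antiviral sensor, at 1.27 ± 0.33, and 6 of 38 members passed adjusted over the list alone. Interferon-gamma response genes were higher by 0.45 ± 0.38 (adjusted p = 0.417 with an estimated correlation), with GBP1 at 1.66 ± 0.39 and the tryptophan-degrading enzyme IDO1 at 1.19 ± 0.30.

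The remaining lists called at week 20 were monocyte markers (0.45 ± 0.64), dendritic cell markers (-0.36 ± 0.28) and ribosomal protein genes (-0.18 ± 0.38). These too were lost with an estimated correlation (adjusted p = 0.551, adjusted p = 0.394 and adjusted p = 0.636 with an estimated correlation). With all 7 monkeys, all 8 calls were lost in this way. The dendritic cell and ribosomal lists also lost their calls without the 5 arrays of high spike-in signal or actin ratio (-0.29 and -0.061). The chaperone HSP90AB1 fell by -0.70 ± 0.13 (adjusted p = 0.0124) in 7 of 7 monkeys. CX3CR1 stood at 0.99 ± 0.23, the death ligand FASLG at 1.37 ± 0.34, CD8A at 0.08 ± 0.24, CD4 at -0.24 ± 0.23, MKI67 at 0.42 ± 0.23, ISG15 at 1.41 ± 0.59 and the antiviral GTPase MX1 at 0.79 ± 0.36. The count of 123 fell to 53 without monkey 3318, 14 without 3333, 19 without 3334 and 33 without 3337, and to 54 (26 higher and 28 lower) without those 5 arrays. Of the 23 named genes that passed, 10 then still did, among them PTX3 (2.08), SAMSN1 (1.06), DPEP2 (-1.83) and CCND3 (-1.0), while the other 13 kept their sign at adjusted p from 0.0557 to 0.127, among them ACSL1, FOXP1, CD37, STAP1 and CDC14A.

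The baseline array of monkey 3336, which went against the other 6 at week 2, also enters the comparisons of weeks 20 and 26 with baseline. Without this monkey, genes that then passed at week 20 were IFI27 (3.39, adjusted p = 0.00718), IFIT3 (1.77, 0.0372), GBP1 (1.57, 0.0446), FASLG (1.67, 0.0207), CD79A (-1.42, 0.0217), BLNK (-1.16, 0.0133), FCRLA (-1.09, 0.0207) and MS4A1 (-1.33, 0.0440). ACSL1, ZNF703, ETS2, CPT1A, FCER1A, TSHZ1, CCDC183 and FOXP1 no longer passed, at adjusted p of 0.0561 (FOXP1) or more, and at week 26 GJC3 did not (0.0731). ISG15 stood at 2.19 at week 20 without this monkey and did not pass (0.0610). The monkey was singled out by its week 2 change, which uses the same baseline array, so these calls are no independent support. Camera with an estimated correlation was also run without this monkey, a fit chosen after the data were seen. At week 20 the B cell list (-0.88, adjusted p = 0.0164) and the inflammatory list (0.58, 0.0412) then passed. The naive and central memory T cell list did not (-0.34, 0.350).

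The comparison of week 26 with baseline set infected monkeys on therapy against their own state before infection. Immediate early genes, which are induced within minutes of cell stimulation, were lower in 7 of 7 monkeys by -1.17 ± 0.37 as a list, with all 18 measured members below baseline and 11 of them passing on their own. FOS, a subunit of the AP-1 transcription factor, fell by -2.19 ± 0.20 (adjusted p = 3.56e-07), the nuclear receptor NR4A2 by -3.17 ± 0.34 (2.74e-06), RGS1, a brake on chemokine receptor signalling, by -2.43 ± 0.28 (6.65e-06) and the transcription factor EGR2 by -1.40 ± 0.22 (0.000289). The chemokine receptor CXCR4 fell by -2.31 ± 0.23 (8.97e-07) and the cytokine IL1B by -2.58 ± 0.34 (3.90e-05), while CX3CR1 rose by 1.77 ± 0.23 (4.98e-05), all in 7 of 7 monkeys. The immediate early list kept its call with an estimated correlation (adjusted p = 0.0231 with an estimated correlation).

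At week 26, 492 probe sets differed from baseline by limma's test, 41 higher and 451 lower, and 408 of them moved the same way in 7 of 7 monkeys. The number higher varied widely, from 4 without monkey 3319 to 109 without 3324, with 80 after quantile normalization and 76 with array weights, and stayed below the number lower in each. Other large falls were in RGCC, a regulator of the cell cycle (-2.89 ± 0.45), CHP2 (-2.63 ± 0.33), GPR183, an oxysterol receptor that guides lymphocytes (-2.04 ± 0.24), FCER1A (-1.91 ± 0.30) and NAF1 (-1.89 ± 0.36). Other large rises were in METTL14, part of the RNA methylation complex (2.14 ± 0.32), GJC3 (1.48 ± 0.38), the oxysterol-sensing nuclear receptor NR1H3 (1.22 ± 0.27), the mitochondrial enzyme PCK2 (1.22 ± 0.32), FAM110A (1.20 ± 0.27), the phospholipid enzyme CEPT1 (0.88 ± 0.21), NFE2, a transcription factor of megakaryocytes (0.87 ± 0.22), OSBP (0.87 ± 0.20) and the mitochondrial ribosomal protein MRPS14 (0.75 ± 0.19). The other probe sets of METTL14 ranged from -0.21 to -0.14 and those of OSBP from -0.52 to -0.22, and the second probe set of CHP2 stood at -0.10.

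The inflammatory list was lower at week 26 by -0.53 ± 0.29 in 7 of 7 monkeys (adjusted p = 0.333 with an estimated correlation), with IL1B and TNFAIP3, a brake on NF-kappaB (-1.71 ± 0.27), passing over all and 3 of 17 members adjusted over the list alone; PTX3 stood at -1.18 ± 0.32. Interferon-stimulated genes were higher by 0.38 ± 0.69 in 5 of 7 monkeys (adjusted p = 0.477 with an estimated correlation). ISG15 stood at 0.82 ± 0.59 and MX1 at 0.67 ± 0.36, while the brightest probe set of OAS1, which makes the activator of RNase L, fell by -1.07 ± 0.12 and its other 4 probe sets ran from -0.78 to 0.33. Interferon-gamma response genes were higher as a list by 0.45 ± 0.60 (adjusted p = 0.417 with an estimated correlation), although the cytokine-signalling inhibitor SOCS1 (-1.55 ± 0.17) and the transcription factor IRF8 (-0.80 ± 0.17) fell; 8 members higher and 2 lower passed adjusted over the list alone. Falls also reached TOX, a transcription factor of chronically stimulated T cells (-0.86 ± 0.18), the pro-apoptotic PMAIP1 (-1.14 ± 0.22), the stress genes HERPUD1 (-0.71 ± 0.13), ATF4 (-0.66 ± 0.13) and HSP90AB1 (-0.62 ± 0.13), and the transferrin receptor TFRC (-0.76 ± 0.16), each in 7 of 7 monkeys.

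Dendritic cell markers were lower at week 26 by -0.41 ± 0.38 and naive T cell markers by -0.30 ± 0.55, and monocyte markers were higher by 0.38 ± 0.76, oxidative phosphorylation genes by 0.11 ± 0.29; heat shock genes were lower by -0.20 ± 0.29. Of these, the smallest adjusted p with an estimated correlation was 0.333. CD8A stood at 0.22 ± 0.24, CD4 at -0.20 ± 0.23, MS4A1 at -0.01 ± 0.37 and MKI67 at 0.66 ± 0.23. The count of 492 became 240 without monkey 3319, 295 without 3333 and 300 without 3337, and 230 without the 5 arrays of high spike-in signal or actin ratio. Without those arrays the immediate early list stood at -1.01, FOS at -2.03, CXCR4 at -1.99 and CX3CR1 at 1.64, and all 4 passed, as did 20 of the 31 named genes that passed with all arrays. The other 11 kept their sign at adjusted p from 0.0561 to 0.185: the rises of GJC3, NR1H3, PCK2, CEPT1, NFE2, OSBP and MRPS14 and the falls of IRF8, TOX, PMAIP1 and HSP90AB1; the naive T cell list (-0.097, over 1.5 times smaller), the dendritic cell list (-0.31) and the heat shock list (-0.14) also lost their calls.

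**Figure D3:**
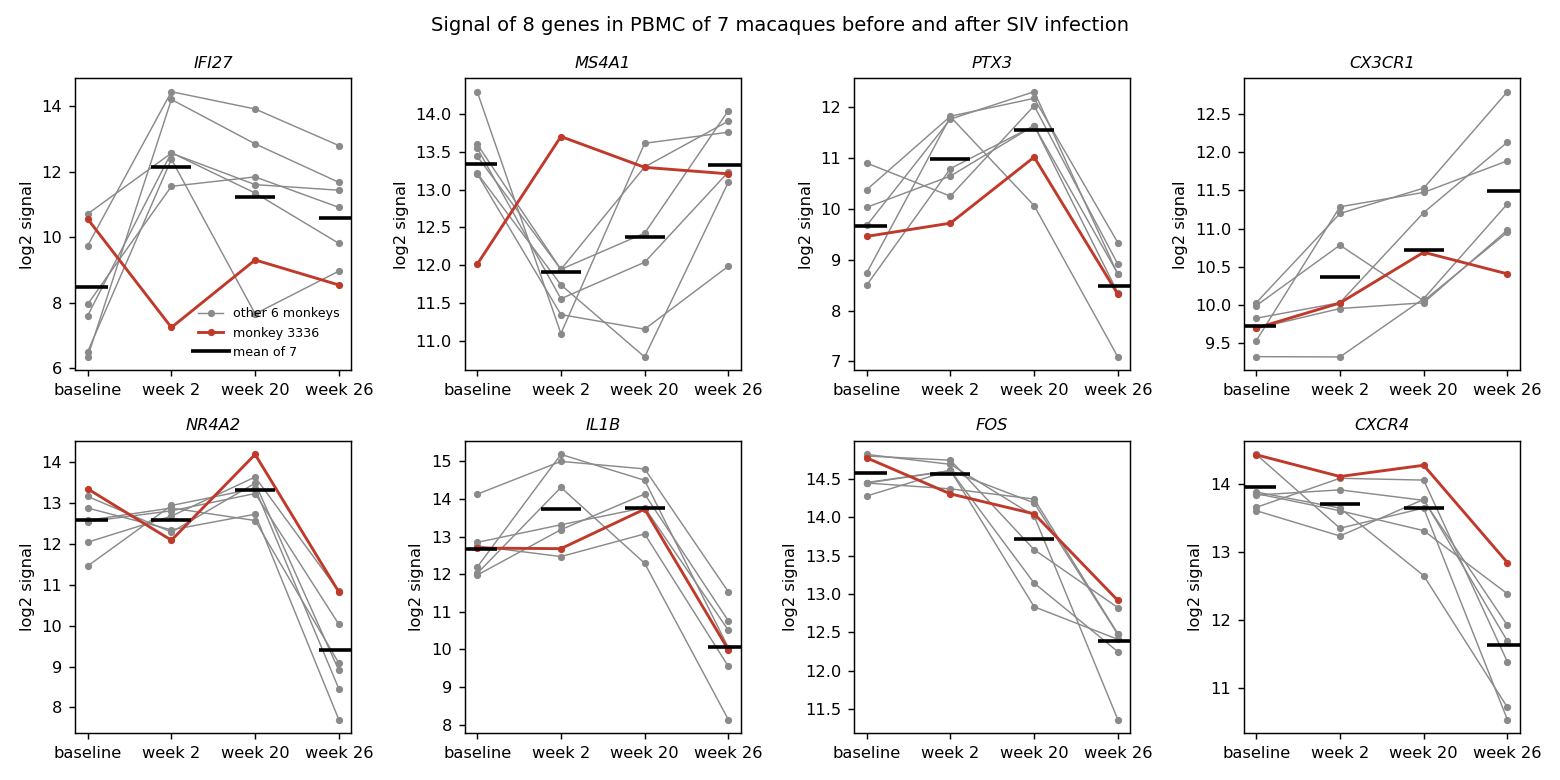
Log2 signal of 8 genes at the 4 time points, with 1 line per monkey, monkey 3336 in red, the other 6 in grey and the mean of 7 as a black bar. NR4A2, IL1B, FOS and CXCR4 were lower at week 26 than at baseline in 7 of 7 monkeys, and CX3CR1 was higher in 7 of 7.

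The comparison of week 26 with week 20 spanned the start of therapy. IL1B fell by -3.68 ± 0.34 (adjusted p = 1.34e-07), NR4A2 by -3.91 ± 0.34 (5.54e-08), PTX3 by -3.06 ± 0.32 (7.71e-07), TNFAIP3 by -2.44 ± 0.27 (2.57e-06) and the neutrophil chemokine CXCL8 by -2.24 ± 0.48 (0.00528), each in 7 of 7 monkeys. The inflammatory list fell by -1.05 ± 0.30 and the immediate early list by -1.21 ± 0.36, both in 7 of 7 monkeys and both kept with an estimated correlation (adjusted p = 0.0231 and adjusted p = 0.0248 with an estimated correlation). ACADM, which oxidises medium-chain fatty acids, rose by 1.91 ± 0.42 (0.00641), the phosphatase CDC14A by 1.66 ± 0.25 (0.000173) and the complement gene C1QA by 1.11 ± 0.25 (0.00768, 6 of 7 monkeys). Interferon-stimulated genes did not pass as a list (-0.08 ± 0.33), with ISG15 at -0.59 ± 0.59 and MX1 at -0.12 ± 0.36.

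Between weeks 20 and 26, 1236 probe sets passed limma's test, 463 higher and 773 lower, and 919 of them moved the same way in 7 of 7 monkeys. The largest named fall was that of CHP2 (-4.13 ± 0.33), whose second probe set stood at -0.11. It was followed by SERPINB2, an inhibitor of plasminogen activators (-3.49 ± 0.43), RGCC (-3.36 ± 0.45), SMAD7, an inhibitor of TGF-beta signalling (-2.55 ± 0.41), and NAF1 (-2.35 ± 0.36). Further large rises were in SLC46A3 (2.12 ± 0.61), CCDC66 (1.58 ± 0.42), TSHZ1 (1.56 ± 0.27), the mitochondrial carrier SLC25A42 (1.5 ± 0.39), TMEM39B (1.49 ± 0.32), the water channel AQP1 (1.39 ± 0.34), SUSD3 (1.38 ± 0.33) and ST8SIA4 (1.36 ± 0.21). The second probe set of TSHZ1 stood at -0.13.

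Of the immediate early genes, 12 of 18 fell over all probe sets tested and 13 adjusted over the list alone, among them EGR2 (-2.16 ± 0.22) and JUND (-1.19 ± 0.17). Of the inflammatory genes, 5 of 17 fell over all and 10 adjusted over the list alone. Heat shock and unfolded protein genes were lower by -0.27 ± 0.20 (adjusted p = 0.525 with an estimated correlation), with HERPUD1 at -0.92 ± 0.13, ATF4 at -0.76 ± 0.13 and HSPH1 at -1.02 ± 0.22 all passing. B cell markers were higher by 0.43 ± 0.47 in 5 of 7 monkeys (adjusted p = 0.477 with an estimated correlation), with 12 of 13 members higher and MS4A1 at 0.94 ± 0.37. Oxidative phosphorylation genes were higher by 0.22 ± 0.22 and ribosomal protein genes by 0.16 ± 0.29, with adjusted p = 0.477 and adjusted p = 0.696 with an estimated correlation.

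Other single genes fell between weeks 20 and 26, among them FASLG (-1.43 ± 0.34), the co-stimulator ICOS (-0.96 ± 0.26, 6 of 7 monkeys), the inhibitory receptor CTLA4 (-0.83 ± 0.24), the survival gene BCL2A1 (-1.46 ± 0.35), the pro-apoptotic PMAIP1 (-0.82 ± 0.22) and BBC3 (-0.80 ± 0.22), SOCS1 (-1.05 ± 0.17), TFRC (-1.18 ± 0.16), the brightest OAS1 probe set (-1.15 ± 0.12) and PRDM1, a regulator of plasma cell and effector T cell fate (-1.16 ± 0.26, 6 of 7 monkeys). The DNA sensor IFI16 rose by 0.59 ± 0.16. CD8A stood at 0.15 ± 0.24, CD4 at 0.03 ± 0.23 and MKI67 at 0.24 ± 0.23. The count of 1236 fell to 660 without monkey 3333 (166 higher), 669 without 3337 (163 higher) and 587 without the 5 arrays of high spike-in signal or actin ratio. Without those arrays the inflammatory list stood at -1.02, the immediate early list at -1.13, IL1B at -3.69 and PTX3 at -3.25, and all 4 passed, as did 28 of the 37 named genes that passed with all arrays. The other 9 kept their sign at adjusted p from 0.0503 to 0.201: FASLG, ICOS, CTLA4, PMAIP1, HSPH1, SLC46A3, CCDC66, SLC25A42 and SUSD3; the ribosomal protein and oxidative phosphorylation lists also lost their calls (0.032 and 0.10, both over 1.5 times smaller).

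The comparison of week 20 with week 2 set established infection against the acute phase. Ribosomal protein genes were lower by -0.33 ± 0.19 in 7 of 7 monkeys, with 16 of 32 passing adjusted over the list alone, and naive and central memory T cell markers were lower by -0.40 ± 0.26 in 7 of 7. Both had adjusted p = 0.333 with an estimated correlation, the smallest of this comparison, so none of its list calls was kept. Of those lists, RPL8 stood at -0.56 ± 0.15, RPL13 at -0.51 ± 0.15, RPS15 at -0.68 ± 0.21, FOXP1 at -0.67 ± 0.15, ABLIM1 at -0.64 ± 0.19, PIK3IP1 at -0.85 ± 0.26 and CAMK4 at -0.64 ± 0.22. Platelet markers were higher by 0.48 ± 0.40, with the adhesion receptor SELP at 1.39 ± 0.29, NRGN at 1.16 ± 0.34 and PPBP at 1.28 ± 0.44. Interferon-stimulated genes were lower by -0.32 ± 0.42 and retroviral restriction factors by -0.28 ± 0.16, with the virion-tethering factor BST2 at -0.83 ± 0.21 and IFITM1, which blocks viral entry, at -0.68 ± 0.18. Oxidative phosphorylation genes (-0.31 ± 0.30), antigen processing genes (-0.18 ± 0.25), monocyte markers (-0.32 ± 0.78) and cytotoxic effector genes (-0.26 ± 0.51) completed the 9 lists called. Without the 5 arrays of high spike-in signal or actin ratio, the ribosomal shift was -0.18 and the oxidative phosphorylation shift -0.19, both still called and over 1.5 times smaller. RPL8 (-0.36), RPL13 (-0.31), RPS15 (-0.35), FOXP1 (-0.44), PIK3IP1 (-0.54) and BST2 (-0.54) were also over 1.5 times smaller.

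Only 9 probe sets passed limma's test between weeks 2 and 20, 3 higher and 6 lower, and 6 of them carry no single gene name here. Of the rest, which were chosen after their values were seen, SAMSN1 rose on both of its probe sets (0.96 and 1.5). The third was a probe set of OAS1 (-0.98), whose other 4 probe sets ran from -0.53 to 0.04. The 3 higher and the 6 lower probe sets were also called in the same direction at week 20 with baseline. Both comparisons use the week 20 arrays. From week 20 to week 26 the 3 were called lower, and 3 of the 6 were called higher. The count of 9 became 3 without monkey 3318, 21 without 3319, 5 without 3324, 3 without 3333, 5 without 3334, and 2 without the 5 arrays of high spike-in signal or actin ratio. Monkey 3319 went against the other 6 here, with r = -0.0873 between its changes and their mean. Of 133 probe sets that separated the 2 times in the other 6, 54 (40.6%) moved the same way in it. The monocyte shift was -0.04 without monkey 3324 and the cytotoxic shift -0.08 without monkey 3318, and neither then passed; the cytotoxic list also lost its call without the 5 arrays (adjusted p = 0.150).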

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

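The tests of explanations and of other splits in this part were chosen after the results they bear on were seen, except the best-match test of array identity and the test on separate monkeys. For the test of both early arrays of monkey 3336 coming from 1 other animal, the rule was also tightened after its value was seen: by rank alone, as first written, 2 of 2 would have argued against that explanation, and the rule now also asks for a lead over the next monkey larger than the SD of the other 6. A value is listed when 1 monkey lay far from the other 6 by Dixon's gap test. Of 305 groups of 7 values tested, 32 were listed, where chance gives about 1 in 20 groups, or 15.25.

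The week 2 arrays of monkey 3336 went against those of the other 6 monkeys in several immune cell groups. Its B cell list changed by 1.20, its cytotoxic list by -0.70 and its natural killer cell list by -0.51. Among single genes, MS4A1 changed by 1.68, CD79A by 1.39, FCRLA by 1.54 and CD1C by 1.39 in this monkey.

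Week 2 with baseline gave 0 probe sets, so each of the 64 exchanges of the 2 time points within monkeys gives as many (64 of 64) whatever the data, and they say nothing on chance there. The highest was 270 probe sets, reached when the 2 arrays of monkey 3336 alone were exchanged, while exchanging those of any other single monkey gave 0 or 1. A count so far above the real one points to a structure of the samples, here the opposite direction of monkey 3336 already seen above; it restates that observation and is no further support for any explanation. The labels were kept throughout.

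For monkey 3336, poor quality of these arrays is argued against, since the lower of their mean correlations with arrays of other monkeys was 0.803 with no high spike-in signal or actin ratio, and so is 1 of them being of another of these monkeys, since 2 of 2 correlated best with each other. Whether both came from 1 other animal cannot be told apart: the week 20 and week 26 arrays of monkey 3336 came first of the 7 monkeys for 2 of 2, but at low mean r (0.0407 and 0.0657, against 0.00968 and 0.0351 for the next). An exchange of its baseline and week 2 arrays may account for the pattern: over 111 probe sets called at week 20 in the other 6 monkeys, its array labelled week 2 differed in mean signed change by -0.512 from its array labelled baseline, while each other monkey, scored over the 14 to 109 probe sets called without it, gave 0.230 to 0.717. Its 2 arrays scored 0.404 (labelled baseline) and -0.108 (labelled week 2), against left-out scores of the others of -0.195 to 0.481 at baseline, a range that holds both, and 0.265 to 0.809 at week 2, which holds the first alone; against a full exchange, its monocyte list changed at week 2 by 0.69, the direction of 5 of the other 6. Over the same 111 probe sets, which were chosen with them, the other 6 lay at -0.140 to 0.287 at baseline and 0.518 to 0.975 at week 2. The score of 0.404 lies in neither range. A truly different course of infection in this animal would give a negative difference too, so the score cannot tell it from an exchange. Such a course stays open and was not tested.

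Week 20 with baseline gave 123 probe sets and was matched by 1 of 64 exchanges, the real one, with 1 probe set as the highest other. Week 26 with baseline gave 492, matched by 1 of 64, with 143 as the highest other (the arrays of monkey 3334 exchanged). Week 26 with week 20 gave 1236, matched by 1 of 64, with 279 as the highest other (monkey 3324 exchanged), and the highest of 36 random splits that put both arrays of some monkeys in one group gave 336. Week 20 with week 2 gave 9, matched by 1 of 64, with 1 as the highest other. Chance is argued against for these 4 counts but not excluded. The share of 1 in 64 (0.0156) is the smallest these exchanges allow. It was not adjusted over the comparisons, which share arrays. The count of 9 ran from 2 to 21 under the alternatives.

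Immediate early and inflammatory genes were lower at week 26, 2 weeks into therapy. The inflammatory list differed by -1.05 between weeks 20 and 26 in its change from baseline, by camera and in 7 of 7 monkeys. Poor arrays are argued against, since the immediate early list stood at -1.01 against baseline without the 5 doubted arrays. For the immediate early list a return to the level before infection is too, since it stood at -1.17 relative to that level. The inflammatory list lay above baseline at week 20, so part of its fall led back to that level. Its call below baseline at week 26 was lost with an estimated correlation. Fewer monocytes as the whole cause are argued against, since the monocyte list stood at -0.065 between weeks 20 and 26. Without the 5 arrays it stood at -0.28, where the inflammatory list stood at -1.02. These genes respond within minutes to how blood is drawn and kept, so sample handling at the week 26 visit could give the same fall. For the inflammatory list, handling at the week 20 visit could likewise add to the fall between weeks 20 and 26. A batch effect common to the week 26 arrays was not tested. With 0 week 26 arrays of animals without therapy, handling, batch and therapy cannot be told apart.

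Changes from baseline to week 20 ran opposite to those from week 20 to week 26 across probe sets (r = -0.552, against -0.499 for simulated unchanged groups, and covariance -0.0953 against -0.0484, over 20 simulations). Both changes use the week 20 arrays, which alone give a negative correlation. With the first change taken from 3 monkeys and the second from the other 4, the mean correlation was -0.177, from -0.291 to -0.0941, below 0 in 35 of 35 splits, which argues against the shared arrays as the whole cause. A partial return of week 20 changes under therapy is a candidate explanation, and a batch effect common to the week 20 arrays stays open and was not tested. Correlations across probe sets are not over independent replicates. The 35 splits reuse the same monkeys, so they are not 35 separate tests. The simulated groups had spread drawn independently for each probe set, unlike real arrays, where probe sets may move together.

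Among array measures, spike-in signal was 3.47 times the median array at week 2 in monkey 3319. The actin 3' to 5' ratio was 2.66 at baseline in monkey 3333, 3.34 at week 2 in monkey 3334 and 5.40 at week 20 in monkey 3324. The GAPDH ratio was 3.83 at week 2 in monkey 3334 and 2.04 at week 20 in monkey 3324.

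Among lists, the T cell inhibitory list changed by 0.34 at week 2 in monkey 3333. At week 26 with baseline, monkey 3318 had restriction factors at -0.75 and dendritic cell markers at -1.16. From week 20 to week 26, monkey 3324 had the cell cycle list at -0.57 and housekeeping genes at 0.45, and monkey 3319 had immediate early genes at -1.94 and apoptosis genes at -0.66. From week 2 to week 20, monkey 3318 had cytotoxic genes at -1.32 and natural killer cell markers at -0.997, and monkey 3324 had monocyte markers at -2.00.

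Among genes, DPEP2 changed by -3.99 at week 20 in monkey 3318 and FOS by -3.46 at week 26 in monkey 3319. From week 20 to week 26, monkey 3318 had AQP1 at 3.32, SMAD7 at -0.66, BCL2A1 at -3.29 and CD8A at 1.24. Over the same weeks monkey 3324 had CDC14A at 3.61 and CTLA4 at -1.65, and monkey 3319 had PMAIP1 at -2.48. Monkeys 3318 and 3319 (at week 26), 3324 and 3336 (at week 20) and 3334 (at week 2) each had an array of high spike-in signal or actin ratio. The week 20 array of monkey 3318 read 3.89 times the median array in spike-in signal, just under the limit of 4.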

How the results depend on the processing

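The fit without the 5 arrays of high spike-in signal or actin ratio and the list test without monkey 3336 with an estimated correlation were chosen after the data were seen, and the other alternatives were planned. Counts are probe sets for week 2, week 20 and week 26 with baseline, week 26 with week 20, and week 20 with week 2, as reported 0, 123, 492, 1236 and 9. The pairing by monkey mattered: without the replicate block the last 4 counts were 14, 247, 659 and 2, 50 of 164 named genes passed instead of 91, and 41 list tests instead of 44. With the monkey as a random effect no count moved by 1.5 times. Similar counts did not mean the same probe sets. For week 20 with baseline, 91 of the 119 called with the random effect were among the 123 reported. With array weights 90 of 121 were, with the 2 compared time points alone 71 of 138, and without monkey 3336 68 of 111. With no floor 122 of 124 were. For week 20 with baseline, the count was 74 with median centring, 63 with no filter and 41 with eBayes without a trend, and 247 with the stricter filter, which tested 13177 probe sets; the cause was not tested. The stricter filter gave 1 for week 2 with baseline, and eBayes without a trend gave 5 for week 20 with week 2. With the 2 compared time points alone, which leaves fewer arrays for the spread, counts were 219, 615 and 4 for the last 3 comparisons. By construction, a threshold of 0.01 gave 17, 225, 488 and 4, and a 2-fold minimum 56, 236 and 527 for weeks 20 and 26 with baseline and week 26 with week 20. Without the 5 arrays, the last 4 counts were 54, 230, 587 and 2. Leaving out 1 monkey gave 0 to 135, 14 to 111, 240 to 526, 660 to 1067 and 3 to 21. Quantile normalization put 14.7% of the week 26 calls against baseline higher and array weights 18.9%, against 8.33%, and each put 50% of the 6 calls for week 20 with week 2 higher, against 33.3%; no scaling moved the median of all probe sets by 0.1.

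Of 125 list tests 44 passed as reported, 36 to 53 under the other alternatives, and 4 with an estimated correlation between genes, which allows for members moving together. That correlation gave 7 by camera without monkey 3336, which was singled out on these same data. B cell markers passed at week 2 (-0.95, adjusted p = 0.0126) and week 20 (-0.88, 0.0164). The inflammatory list passed at week 2 (0.71, 0.0411), at week 20 (0.58, 0.0412) and from week 20 to week 26 (-1.05, 0.0273). The immediate early list passed at week 26 against baseline (-1.18, 0.0273) and against week 20 (-1.22, 0.0412). At the preset correlation, leaving out 1 monkey gave 37 to 48. Of 3583 values of named genes under alternatives, 26 changed sign, of which 22 were small and uncalled; of 2625 list values 180 did, of which 177 were small and uncalled. The remaining ones were OSBP at week 26 (-0.027 with the mean of its probe sets, which disagree), CD4 at week 26 (from -0.36 to 0.041 when 1 monkey was left out, the latter without 3319), MKI67 from week 20 to week 26 (-0.10 with the mean of its probe sets, -0.078 without the 5 arrays) and the T cell inhibitory list from week 2 to week 20 (-0.084 with no filter, -0.055 with the pseudocount, -0.038 with the higher floor); apart from OSBP these were not called as reported, and the cause was not tested. For lists, the random block and robust eBayes were planned and not run, and the stricter filter gave a value for 139 of 164 named genes, of which 77 passed. Without detection calls, how many dim probe sets lay above background is unknown here, so a missing call among them says little.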

Other observations

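The simulated and separate-monkey values for the pair of week 2 and week 20 changes, given last, and the fit without monkey 3336 with an estimated correlation were chosen after the results were seen, and the other tests in this part before it. With all 7 monkeys, several immune cell groups showed no shift past the test at any time. Some of this rested on monkey 3336: without it, CD8 T cell markers passed at week 2 (0.43, adjusted p = 0.00954), T cell markers from week 2 to week 20 (-0.30, 0.00659), and cell cycle genes at week 2 (0.14, 0.0490) and week 20 (0.16, 0.0315), both over 1.5 times the values with all monkeys. With an estimated correlation none of these 4 passed (adjusted p = 0.238, 0.338, 0.225 and 0.195 with an estimated correlation). Without monkey 3336 and at the preset correlation, cytotoxic genes at weeks 20 and 26, B cell markers at week 26 and housekeeping genes from week 2 to week 20 also passed. Each had adjusted p = 0.350 or more with an estimated correlation. Ribosomal protein genes at week 20 and from week 20 to week 26, and heat shock genes at week 26 and from week 20 to week 26, no longer passed. Without monkey 3336 and with an estimated correlation, B cell markers at weeks 2 and 20 and inflammatory genes at week 20 did pass. T cell markers stood at 0.01 ± 0.40 (SD, n = 7) at week 2, -0.21 ± 0.16 at week 20 and -0.21 ± 0.35 at week 26 against baseline, with 7 of 7 monkeys lower at week 20. CD8 T cell markers stood at 0.31 ± 0.49, 0.06 ± 0.40 and 0.13 ± 0.23. Natural killer cell markers stood at 0.12 ± 0.29, -0.18 ± 0.42 and -0.14 ± 0.44, and were lower from week 2 to week 20 in 7 of 7 monkeys (-0.30 ± 0.33). T cell inhibitory receptors stood at 0.00, 0.05 ± 0.20 and -0.03 ± 0.28 as a group, although CTLA4 and ICOS fell from week 20 to week 26 and TOX fell from baseline to week 26. Plasma cell genes stood at -0.09 ± 0.27, 0.00 and 0.02 ± 0.26, so the lower B cell markers at weeks 2 and 20 had no counterpart of that size there; the difference was not tested.

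With all 7 monkeys, cell cycle genes stood at 0.08 ± 0.19, 0.10 ± 0.19 and 0.00 against baseline, and apoptosis genes at -0.03 ± 0.14, 0.06 ± 0.21 and -0.14 ± 0.18. Apoptosis genes were lower from week 20 to week 26 in 7 of 7 monkeys (-0.20 ± 0.21; camera, adjusted p = 0.110), with 6 of 20 members lower and 1 higher adjusted over the list alone. Erythroid markers stood at 0.34 ± 0.31, 0.30 ± 0.46 and 0.34 ± 0.27 and granulocyte markers at 0.25 ± 0.30, 0.19 ± 0.17 and 0.13 ± 0.40, each over 6 measured genes and none past the test. Housekeeping genes stood at 0.09 ± 0.17, -0.07 ± 0.28 and -0.06 ± 0.33. Members overlap between lists, such as TNFAIP3 in the immediate early and the inflammatory list, and CCL3 in the cytotoxic and the inflammatory list.

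The exact two-sided sign-flip permutation test reached its smallest p, 0.0156, for lists that moved the same way in 7 of 7 monkeys, which is 0.140 after adjustment over 125 tests, so no list passes by that test. Fry called 1, 1, 1, 2 and 0 lists for weeks 2, 20 and 26 with baseline, week 26 with week 20, and week 20 with week 2. In the 44 list tests called, the mean, the median and the test had the same sign. The mean and the test differed in sign for uncalled lists, such as interferon-stimulated genes from week 20 to week 26 (mean -0.08, median 0.03, test upward).

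Of 28 arrays, 23 correlated best with another array of the same monkey once the mean of each probe set was removed. The week 20 and week 26 arrays of monkey 3336 were among the 5 others. So were the baseline and week 26 arrays of monkey 3334 and the week 2 array of monkey 3324. The week 26 array of monkey 3334 correlated best with the week 26 array of monkey 3337 (r = 0.323).

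Changes at week 2 and week 20, both against baseline, correlated across probe sets at r = 0.512, against 0.502 for simulated unchanged groups that share the baseline (covariance 0.0638 against 0.0488). With the 2 changes taken from separate monkeys, the mean r was 0.139, from 0.0609 to 0.245 over 35 splits. Probe sets are not independent replicates, and the 35 splits reuse the same monkeys.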
